A study of Homo sapiens with 12 samples.

How the data were processed

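RNA of HCT116 cells was sequenced in 12 libraries, 6 untransfected and 6 transfected, and the groups were taken from the sample records. Untransfected cells received DMSO, 5-FU (375 uM) or Nutlin3a (10 uM) for 8 h, with 2 libraries per group. Transfected cells received siCtrl or GLIS2 siRNA 1 or 2 for 48 h and then DMSO or 5-FU for 8 h, with 1 library per siRNA and treatment, so that a siCtrl group held 1 library and a siGLIS2 group held 2. Per the labels' protocols, libraries were made from poly(A) RNA with a kit that does not mark strand, so overlapping and antisense genes are uncertain.

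Values were FPKM per gene symbol, per the file headers. TopHat2 2.1.1 and Cufflinks 2.2.1 were named per the submitters' processing notes, without their role or order. The notes named a human and a mouse genome build for the series, so no coordinates are given. Untransfected libraries listed 26485 symbols and transfected libraries 25483, 24910 of them in both. The transfected tables repeated some names, whose values were summed, and held entries that join several names by commas, which were treated as features of their own. The values came from separate quantifications, so both experiments were tested only within themselves. No read counts were given, so no counting intervals could be computed and exact zeros are described as listed at 0. In transfected libraries, 44.1 to 47.5 percent of low values fell on steps, which gave depths of 0.818 to 1.04 relative to siCtrl in DMSO. Untransfected values (2.95 to 4.84 percent) allowed no such estimate. Short RNA features (microRNA, small nucleolar and small nuclear RNA names and the like) took 0.786 to 1.02 percent of FPKM in untransfected and 4.63 to 6.39 percent in transfected libraries. Replicates of a group correlated at 0.987 to 0.993 across genes, and siRNA 1 and siRNA 2 libraries of a treatment at 0.957 and 0.958.

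Genes with a mean of at least 1 FPKM over the 6 libraries of an experiment were tested on log2(FPKM+1) with limma 3.58.1 in R 4.3.3 (group means, contrasts, empirical Bayes moderation with a trend on expression, two-sided), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. All groups of an experiment shared a single estimate of the spread. In transfected cells that estimate came from the difference between siRNA 1 and siRNA 2, and the lone siCtrl libraries were assumed to vary alike. The contrasts were 5-FU against DMSO, Nutlin3a against DMSO and 5-FU against Nutlin3a in untransfected cells, and the GLIS2 knockdown averaged over treatments, in DMSO and in 5-FU, its interaction with 5-FU, and 5-FU against DMSO in transfected cells. An additive model of siRNA (siCtrl, siRNA 1, siRNA 2) and drug, without short RNA features, was added after seeing the data. It takes siRNA 1 and siRNA 2 as separate reagents over both treatments. Each siRNA and treatment held 1 library, so its spread is the departure from added siRNA and drug effects, not variation between replicates. A siRNA by drug interaction counts as spread there. Standard errors are those of limma, and "did not pass" refers to the adjusted p.

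The contrasts, filters, 21 gene lists, alternatives and the rule for named genes were fixed before the data were examined. Lists covered p53 targets in the cell cycle and feedback, in cell death, and in DNA repair and metabolism, G2/M genes, G1/S and DNA replication genes, pyrimidine metabolism, ribosome biogenesis, cytosolic ribosomal proteins, histones, immediate early genes, NF-kB genes, interferon-stimulated genes, the integrated stress response, unfolded protein and heat shock genes, cholesterol synthesis, hypoxia and glycolysis, Hedgehog genes, Wnt targets, epithelial and mesenchymal genes, mitochondrially encoded genes, and markers of other cell types. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and contrasts of an experiment, and again with an estimated correlation. List medians, means and counts are over measured members. With an estimated correlation 2 of 14 called lists passed for 5-FU and 2 of 9 for Nutlin3a, and 0 in the other contrasts. A rotation test of each list, limma's fry, was run beside camera. It called 11 lists for 5-FU, 8 for Nutlin3a and 10 between drugs, but 0 in every contrast of transfected cells. Named genes were, per contrast, the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, up to 4 members of each described list with the smallest p, and always 8 fixed genes, among them GLIS2, CDKN1A, MDM2, BBC3, BAX, FAS and GDF15. Some genes that this rule covers are not reported here. Named after their values were seen were TYMS with 5-FU, PCNA with Nutlin3a, the summed level of MTPN and LUZP6, E2F2 for the interaction, AURKA, MCM5, KLK6, KRT23, VCL, ANXA2 and SREBF2 with siRNA 2, and ANKRD1, CYR61, CPA4, FOLR1, ELK3 and PTGES3 with siRNA 1. For single libraries, list medians are differences of log2(FPKM+1) between library pairs and have no test.

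Shared calls are set beside the number that independent calls would give, and correlations of fold changes are across genes, which are not independent replicates. Where both comparisons used the same controls, 20 simulations without an effect gave the value that shared controls produce under independent noise of the fitted spread. In the additive model that spread leaves out any departure of siCtrl common to both treatments. The controls were too few to be split. Pairing was checked by correlating the difference between replicate 1 and replicate 2 across groups: it was 0.53 between siGLIS2 in DMSO and in 5-FU, or 0.73 without short RNA features, where the number names the siRNA per the labels.

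The gene tests were tested on simulated data with 200 changed genes. The list test at the preset correlation was tested on simulated independent genes with the cell-death list shifted by 0.5, and it called that list and no other in all 6 contrasts simulated. For 5-FU in untransfected cells limma recovered 70.1 percent of genes changed 1.5-fold and 97.0 percent of those changed 2-fold, with 13 false calls, and for Nutlin3a 58.2 and 98.5 percent with 13. For the averaged knockdown it recovered 1.49 percent at 1.5-fold, 19.4 percent at 2-fold and 92.4 percent at 4-fold, and for 5-FU in transfected cells 0, 29.9 and 97.0 percent. For siRNA 1 in the additive model it recovered 59.7 percent at 1.5-fold, with 12 false calls, and for 5-FU in that model 92.5 percent, with 25. Simulated libraries had independent noise and no siRNA by drug interaction, so these percentages hold only for such data. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median scaling, quantile normalization, no trend, the replicate or siRNA number as a block, only the groups compared, an additive model, repeated names as separate features, and each library left out in turn (with 4 group means only the siGLIS2 libraries, as a siCtrl group held 1). Gene lengths were matched by symbol to GENCODE 29 (95.4 and 93.0 percent of tested genes outside short RNA), and trends on length were fitted by a local regression with a span of 0.3. Other data of the series were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.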

Results

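HCT116 cells, a colorectal cancer line, were profiled by RNA sequencing in separate experiments. In the first, cells received DMSO, 375 uM 5-fluorouracil (5-FU) or 10 uM Nutlin3a for 8 h, with 2 libraries per group. In the other, which addressed GLIS2 as a repressor of p53 target genes, cells were transfected with a control siRNA (siCtrl) or with either of 2 siRNAs against GLIS2 (siGLIS2) for 48 h and then received DMSO or 5-FU for 8 h, with 1 siCtrl library per treatment and 1 library per GLIS2 siRNA and treatment. Values are FPKM, and changes are log2 fold changes of FPKM+1 given as estimate±standard error, a scale that understates the change of genes near 0 FPKM. No counts were given, so the depth of the untransfected libraries is unknown. The sums of FPKM were 414789 to 466837 in the first experiment and 438436 to 527968 in the other. The p-values of single genes measure only the spread between these libraries. That spread may be technical, because nothing in the sample records says that the libraries came from separate cultures. List p-values of camera at the preset correlation set list genes against the other genes, treating genes as nearly independent. They can thus be very small with few libraries and do not measure the spread between libraries alone. With an estimated correlation most list calls did not pass.

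5-FU, a pyrimidine analog that damages DNA and disturbs RNA processing, raised known targets of p53. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 98.6 to 643 FPKM (n = 2 per group, log2 fold change 2.69±0.11). MDM2, the ubiquitin ligase that degrades p53, rose from 15.1 to 60.5 FPKM (1.93±0.09), and PPM1D, a phosphatase that dampens p53 signaling, rose by 1.96±0.08. PHLDA3, an inhibitor of AKT, increased by 2.42±0.08. Of 29 measured p53 targets with roles in the cell cycle and in feedback, 25 rose, 0 fell and 4 did not pass (limma camera test of the list, median 1.54, adjusted p = 4.3e-23, or 0.027 with an estimated correlation). Adjusted over the list alone, 26 rose and 1 fell.

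Targets of p53 that act in cell death rose as a group with 5-FU. BBC3, which encodes the BH3-only protein PUMA, went from 13.4 to 57.3 FPKM (2.02±0.09), FAS, a death receptor, from 5.58 to 31.7 FPKM (2.31±0.11), and BAX, the pore-forming effector of mitochondrial apoptosis, from 60.8 to 139 FPKM (1.17±0.09). TP53I3, a quinone oxidoreductase gene (PIG3), rose by 2.56±0.09, and PIDD1, whose product assembles a platform for caspase-2, by 1.61±0.08. In this list 17 of 18 members rose, and 18 rose when adjusted over the list alone (median 1.39, adjusted p = 1.0e-20, or 0.080 with an estimated correlation). Targets in DNA repair and metabolism moved less: 16 of 27 rose, or 22 over the list alone (median 0.60, adjusted p = 1.5e-13, or 0.048 with an estimated correlation). Its strongest members were FDXR, a mitochondrial electron-transfer reductase (2.12±0.09), TIGAR, a fructose bisphosphatase (1.31±0.11), CMBL, a hydrolase (1.27±0.09), and ACER2, a ceramidase (1.31±0.11). GDF15, a secreted stress cytokine, rose from 273 to 961 FPKM (1.81±0.18). Outside the lists, SERPINB5, the serpin maspin (2.57±0.10), and UNC5B-AS1, an antisense transcript (2.44±0.17), were among the 6 largest rises. The largest rise was LUZP6 (3.57±0.22), a reading frame inside the MTPN transcript. MTPN and LUZP6 together went from 60.4 to 32.6 FPKM, so both names together had a lower sum.

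Mitotic genes fell with 5-FU. PLK1, a kinase that drives mitotic entry, dropped from 151 to 35.0 FPKM (log2 fold change -2.07±0.11), CDC20, an activator of the anaphase-promoting complex, from 284 to 107 FPKM (-1.40±0.09), AURKA, a spindle kinase, from 51.3 to 16.2 FPKM (-1.61±0.14), and BUB1, a spindle checkpoint kinase, from 38.6 to 15.0 FPKM (-1.30±0.12). Among the largest falls were PIF1, a DNA helicase (-2.89±0.20), and FAM72C (-2.32±0.16). SYS1-DBNDD2, a read-through transcript, was listed at 0 in both 5-FU libraries and at 4.39 and 2.22 FPKM in DMSO. In the list of G2/M and mitosis genes 28 of 35 fell, none rose and 7 did not pass (median -0.91, adjusted p = 2.0e-15, or 0.48 with an estimated correlation). Part of the G1/S and DNA replication genes rose. CCNE2 and CCNE1, the cyclins E that start S phase, rose from 8.25 to 40.0 FPKM (2.14±0.16) and from 26.9 to 66.9 FPKM (1.28±0.11), PCNA, the replication clamp and a p53 target, from 252 to 601 FPKM (1.24±0.13), and RRM2, a ribonucleotide reductase subunit, by 0.86±0.11. Of 36 genes in this list 13 rose, 1 fell and 22 did not pass (median 0.23, adjusted p = 4.3e-06, or 0.49 with an estimated correlation). Replication-dependent histone genes, which poly(A) selection measures poorly, had 0 up and 1 down of 9 (median -0.26, adjusted p = 0.16), the fall being HIST3H2A (-1.02±0.14).

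Nucleotide and ribosome genes responded in part. CAD, the enzyme of the first steps of pyrimidine synthesis, fell (-0.67±0.09), whereas UCK1, a uridine-cytidine kinase (0.72±0.11), TK1, thymidine kinase (0.58±0.10), and CTPS1, which makes CTP (0.51±0.08), rose. TYMS, the thymidylate synthase that 5-FU inhibits, was singled out after its values were seen and rose by 0.34±0.10, which passed narrowly (limma, adjusted p = 0.047). The pyrimidine list had 8 up and 2 down of 26 (median 0.16, adjusted p = 0.033, or 0.64 with an estimated correlation). Ribosome biogenesis genes had 1 up and 8 down of 45 (median -0.15, adjusted p = 0.034, or 0.48 with an estimated correlation), with falls of NAT10, an RNA acetyltransferase (-0.59±0.10), RRP9, a U3 snoRNP protein (-0.59±0.10), and UTP20, a processome component (-0.60±0.13). Cytosolic ribosomal protein genes had 5 up and 0 down of 45, for example RPS20 (0.57±0.13) and RPS19 (0.52±0.14). Adjusted over the list alone none passed, although 43 of 45 values were positive (median 0.31, adjusted p = 7.7e-08, or 0.63 with an estimated correlation). The median was 0.403 and 0.473 in library pairs with 5-FU replicate 1, but 0.136 and 0.187 with replicate 2. Quantile normalization ended this list call.

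Stress and signaling programs split under 5-FU. ATF3, a stress transcription factor, rose from 6.12 to 24.1 FPKM (1.83±0.13), and IER5 (1.06±0.09) and CYR61, a matricellular protein gene (1.16±0.14), rose as well, while MYC fell from 155 to 103 FPKM (-0.59±0.08). Immediate early genes had 9 up and 3 down of 27 (median 0.18, adjusted p = 0.0059, or 0.50 with an estimated correlation). Their median was 0.080 and 0.143 in library pairs with 5-FU replicate 1, and 0.370 and 0.363 with replicate 2. Genes of the integrated stress response and of amino acid supply mostly fell: SLC7A11, a cystine transporter, from 9.13 to 2.04 FPKM (-1.74±0.12), CHAC1, which degrades glutathione, from 18.7 to 4.13 FPKM (-1.95±0.18), and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-1.86±0.15), against a rise of SESN2, which is also a p53 target (1.15±0.09). That list had 3 up and 18 down of 30, and 21 fell over the list alone (median -0.59, adjusted p = 5.0e-07, or 0.38 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response (-0.98±0.10), HERPUD1, of protein degradation at the endoplasmic reticulum (-0.74±0.12), and HSPA8, a constitutive chaperone (-0.77±0.17), fell in a list with 1 up and 9 down of 25 (median -0.19, adjusted p = 0.045, or 0.48 with an estimated correlation). NF-kB and inflammatory genes had 4 up and 0 down of 9 (median 0.36, adjusted p = 0.0022, or 0.34 with an estimated correlation), with IRF1, an interferon regulatory factor (0.91±0.15), and NFKBIA, the inhibitor of NF-kB (0.62±0.09), up. Interferon-stimulated genes had 5 up and 1 down of 22 (median 0.21, adjusted p = 0.0046, or 0.50 with an estimated correlation), among them TLR3, a sensor of double-stranded RNA (1.47±0.16), and ISG15 (0.82±0.13). Hypoxia and glycolysis genes had 4 up and 1 down of 23 (median 0.18, adjusted p = 0.018, or 0.38 with an estimated correlation).

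The other lists did not pass under 5-FU. GLIS, GLI and Hedgehog genes had 0 up and 4 down of 10 (median -0.29, adjusted p = 0.16), with GLI1, an effector of Hedgehog signaling, at 2.15 and 1.80 FPKM in DMSO and 0.599 and 0.800 in 5-FU (-0.81±0.15). GLIS2 did not pass (0.22±0.14, adjusted p = 0.26). Wnt target genes had 2 up and 4 down of 16 (median -0.06, adjusted p = 0.70). Their median turned to 0.01 after median scaling. Epithelial and mesenchymal genes had 3 up and 1 down of 20 (median 0.01, adjusted p = 0.58), and here the median turned to -0.03 after quantile normalization. ESRP1, an epithelial splicing regulator, fell (-1.11±0.09), and ACTA2, a smooth muscle actin and p53 target (1.03±0.12), rose. Cholesterol synthesis genes had 2 up and 1 down of 25 (median 0.04, adjusted p = 0.58), and SQLE, squalene epoxidase, was the single fall (-0.73±0.09). None of the mitochondrially encoded genes was measured, and of the markers of other cell types only COL1A1 and CD68 reached 1 FPKM on average, too few for a list test, and both rose with 5-FU (2 up and 0 down of 2, median 0.48).

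Across 12165 tested genes, 1212 rose and 1627 fell with 5-FU (limma's two-sided moderated test, adjusted p under 0.05), and 174 and 117 of these changed at least 2-fold. The split depended on scaling: after median scaling 1629 rose and 1216 fell, and after quantile normalization 1364 and 1433. With a single DMSO library the total dropped from 2839 to 752 (without DMSO replicate 1) or 628 (without DMSO replicate 2). Without 5-FU replicate 1 or 2 it was 2123 or 4152.

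Nutlin3a, which frees p53 by blocking its binding to MDM2, raised p53 targets as well, several of them further than 5-FU did. TP53I3 rose from 8.50 to 138 FPKM (n = 2 per group, log2 fold change 3.87±0.09), MDM2 from 15.1 to 178 FPKM (3.47±0.09), and CDKN1A from 98.6 to 1026 FPKM (3.36±0.11). BTG2, an antiproliferative p53 target, rose by 2.87±0.11, and TP53INP1, a p53-inducible nuclear protein gene, by 2.85±0.11. All 18 measured cell-death targets rose (median 1.36, adjusted p = 1.2e-23, or 0.077 with an estimated correlation), with BBC3 at 59.4 FPKM (2.07±0.09), FAS at 36.6 (2.51±0.11), BAX at 131 (1.10±0.09), and DRAM1, an autophagy regulator, rising by 1.72±0.10. Of the cell-cycle and feedback targets 27 of 29 rose (median 1.54, adjusted p = 4.9e-32, or 0.027 with an estimated correlation), and of the repair and metabolism targets 24 of 27 (median 1.16, adjusted p = 1.3e-24, or 0.027 with an estimated correlation). None fell in either list. FDXR (2.17±0.09), ACER2 (1.98±0.11) and NADSYN1, an NAD synthetase gene (1.35±0.09), led the repair and metabolism list. SERPINB5 (3.21±0.10) and UNC5B-AS1 (2.90±0.17) were again among the 6 largest rises, and GDF15 rose by 1.90±0.18.

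Nutlin3a lowered mitotic genes and, unlike 5-FU, also the genes of G1/S and DNA replication. PLK1 fell from 151 to 57.2 FPKM (-1.39±0.11), CENPA, the centromeric histone, from 22.2 to 7.30 FPKM (-1.49±0.16), and CDC20 (-1.03±0.09) and ESPL1, which encodes separase (-0.97±0.11), fell too. The G2/M list had 0 up and 29 down of 35 (median -0.76, adjusted p = 1.9e-21, or 0.38 with an estimated correlation). UHRF1, which maintains DNA methylation, fell from 48.7 to 17.0 FPKM (-1.47±0.09), ORC1, of the origin recognition complex, from 24.7 to 9.47 FPKM (-1.29±0.09), MCM2, a subunit of the replicative helicase, from 113 to 53.5 FPKM (-1.07±0.09), and MCM10, a replication initiation factor, fell as well (-1.13±0.09). In the G1/S list 30 of 36 fell and 1 rose (median -0.70, adjusted p = 4.2e-23, or 0.29 with an estimated correlation). The rise was PCNA (0.55±0.13), named after its values were seen. ZNF367, a zinc finger gene (-1.60±0.11), and LSM4, an RNA-binding protein gene (-1.50±0.31), were among the 6 largest falls, with the short RNA features MIR6775 (-1.68±0.28) and MIR6893 (-1.60±0.33), which this library type does not measure well.

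Other groups moved less with Nutlin3a. UNG, uracil-DNA glycosylase (-1.01±0.10), and DCK, deoxycytidine kinase (-0.60±0.12), fell in a pyrimidine list with 1 up and 4 down of 26 (median -0.15, adjusted p = 0.026, or 0.64 with an estimated correlation). Ribosome biogenesis genes had 1 up and 3 down of 45 (median -0.13, adjusted p = 0.0044, or 0.38 with an estimated correlation), with UBTF, a factor of RNA polymerase I (-0.55±0.10), down. Integrated stress response genes had 3 up and 9 down of 30 (median -0.26, adjusted p = 0.0016, or 0.50 with an estimated correlation): TRIB3, a pseudokinase, fell from 56.3 to 27.8 FPKM, and NUPR1, a stress-induced regulator (1.85±0.19), and SESN2 (0.95±0.09) rose. Unfolded protein genes had 7 up and 0 down of 25 (median 0.10, adjusted p = 0.031, or 0.48 with an estimated correlation), with HSPA5, the chaperone BiP, up from 267 to 383 FPKM (0.52±0.08) and HYOU1 by 0.46±0.08. The remaining lists did not pass: ribosomal proteins (0 up and 0 down of 45; median 0.09, adjusted p = 0.070), histones (0 up and 0 down of 9; median -0.06, adjusted p = 0.42), immediate early genes (3 up and 1 down of 27; median -0.14, adjusted p = 0.75) and NF-kB genes (1 up and 0 down of 9; median -0.03 but mean 0.06, adjusted p = 0.99). Interferon-stimulated genes had 2 up and 0 down of 22 (median 0.14, adjusted p = 0.097), Wnt targets 2 up and 0 down of 16 (median 0.22, adjusted p = 0.097), and GLIS, GLI and Hedgehog genes 0 up and 2 down of 10 (median -0.02, adjusted p = 0.45). Medians and means differed in sign for cholesterol synthesis (3 up and 2 down of 25; -0.02 and 0.03, the median turning to 0.000830 after quantile normalization, adjusted p = 0.79), for hypoxia and glycolysis (2 up and 0 down of 23; -0.07 and 0.03, adjusted p = 0.88), and for epithelial and mesenchymal genes (5 up and 2 down of 20; -0.10 and 0.14, adjusted p = 0.91), where ACTA2 nevertheless rose from 2.08 to 13.0 FPKM (2.19±0.12). GLIS2 did not pass (0.03±0.14, adjusted p = 0.92).

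Of 12165 tested genes 807 rose and 721 fell with Nutlin3a (limma), 187 and 56 of them at least 2-fold. The larger side depended on scaling and filter: 734 rose and 843 fell after median scaling, 794 and 877 after quantile normalization, and 622 and 690 with a filter at 5 FPKM. This total of 1528 moved with each library left out: 446 and 469 without DMSO replicate 1 and 2, 607 and 694 without Nutlin3a replicate 1 and 2, but 2403 and 2394 without 5-FU replicate 1 and 2, because the 5-FU libraries add to the shared estimate of the spread.

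Set against each other directly, both drugs differed most in the genes of S-phase entry. CCNE2 stood at 40.0 FPKM with 5-FU and 2.58 with Nutlin3a (log2 difference 3.50±0.16), CCNE1 at 66.9 and 10.8 (2.52±0.11), E2F2, an E2F transcription factor, at 18.6 and 4.41 (1.86±0.11), and UNG at 85.6 and 30.4 (1.47±0.10). UHRF1 (1.49±0.09), ZNF367 (2.15±0.11) and LHX2, a LIM homeobox gene (1.96±0.12), were also higher with 5-FU. In the G1/S list 34 of 36 genes were higher with 5-FU and none lower (median 0.93, adjusted p = 1.6e-26, or 0.27 with an estimated correlation). The pyrimidine list followed (11 up and 3 down of 26; median 0.23, adjusted p = 3.2e-04, or 0.49 with an estimated correlation), with TK1 (0.89±0.10), UCK1 (0.92±0.11) and DCK (0.83±0.12) higher. Mitotic genes did not differ as a list (4 up and 13 down of 35; median -0.10, adjusted p = 0.47), and their median turned to 0.01 after median scaling. PLK1 was lower with 5-FU (-0.68±0.11) and CCNA2, cyclin A, higher (0.81±0.15).

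**Figure D1:**
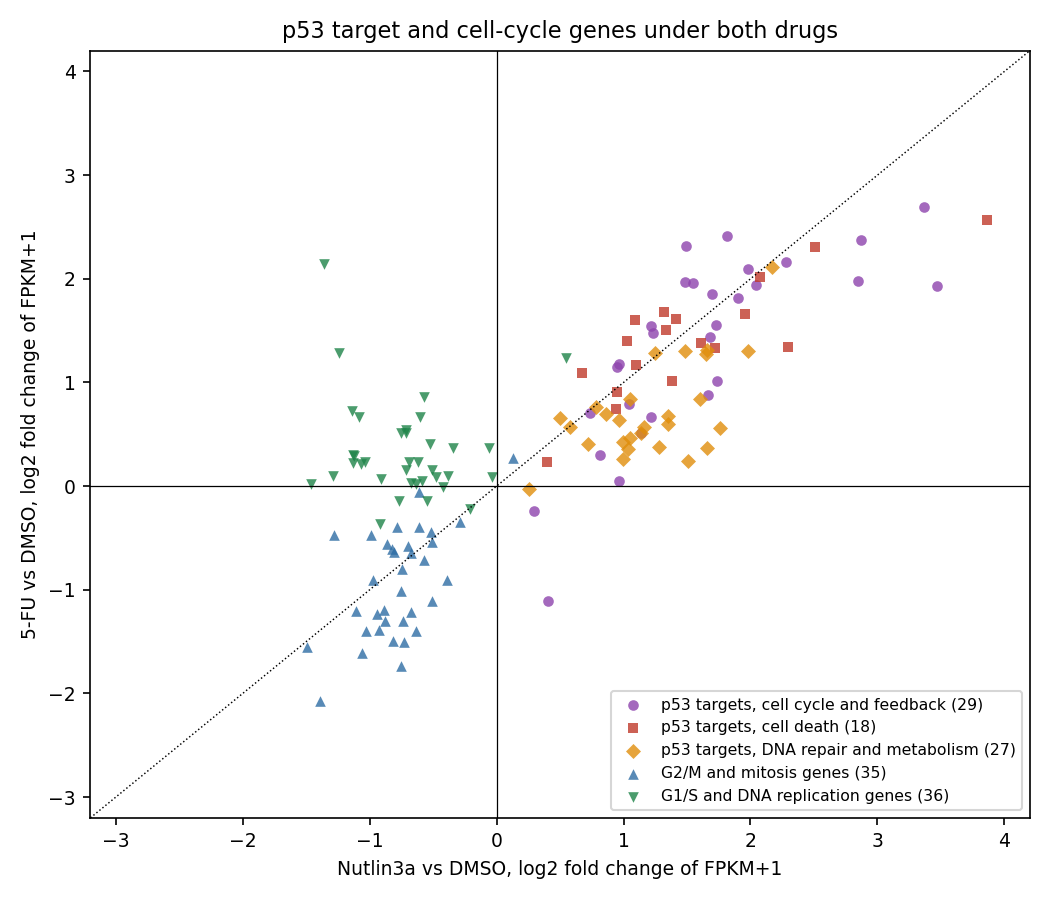
Log2 fold change of FPKM+1 against DMSO with Nutlin3a (horizontal axis) and with 5-FU (vertical axis), a point per measured member of 5 gene lists, dotted line at equal change. Most p53 targets lay in the upper right and most mitotic genes in the lower left, whereas G1/S genes had a median of -0.70 with Nutlin3a and 0.23 with 5-FU.

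Nutlin3a exceeded 5-FU in part of the p53 program. MDM2 (-1.54±0.09), TP53I3 (-1.30±0.09) and CDKN1A (-0.68±0.11) were lower with 5-FU, as were XPC, a damage-recognition factor of nucleotide excision repair (-0.90±0.09), and ANKRA2, an ankyrin repeat gene (-1.26±0.13). Repair and metabolism targets were lower with 5-FU as a list (0 up and 14 down of 27, median -0.57, limma's camera, adjusted p = 1.0e-05, or 0.11 with an estimated correlation). Longer genes tended to be lower in this comparison (Spearman correlation -0.317). After subtracting a trend on gene length the list's median was -0.31, with 24 of 27 values below 0. The cell-cycle list (4 up and 12 down of 29, median -0.18, adjusted p = 0.26) and the cell-death list (4 up and 3 down of 18, median -0.11, adjusted p = 0.96) did not pass. PHLDA3 (0.60±0.08) and PIDD1 (0.51±0.08) were higher with 5-FU, and BBC3 (-0.05±0.09, adjusted p = 0.68), BAX (0.08±0.09, adjusted p = 0.55) and FAS (-0.20±0.11, adjusted p = 0.19) did not pass. NEAT1, a long noncoding RNA of paraspeckles (-1.78±0.13), C1RL, a complement-related protease gene (-1.83±0.16), and MTPN (-1.75±0.09) were among the largest differences toward Nutlin3a. MTPN and LUZP6 together stood at 32.6 FPKM with 5-FU and 61.9 with Nutlin3a, a smaller difference than that of MTPN alone. PLA2G4B, a phospholipase gene, was listed at 0 in both 5-FU libraries and at 4.67 and 3.86 FPKM with Nutlin3a, but also at 0 and 3.67 in the DMSO libraries.

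Stress programs separated both drugs as well. HSPA5 (-0.87±0.08), XBP1 (-1.05±0.10) and SEL1L, of protein quality control (-1.11±0.13), were lower with 5-FU in the unfolded protein list (0 up and 12 down of 25; median -0.45, adjusted p = 0.0025, or 0.38 with an estimated correlation), and SLC7A11 (-1.53±0.12) and PCK2 (-1.05±0.15) in the integrated stress response list (0 up and 11 down of 30; median -0.33, adjusted p = 0.0025, or 0.50 with an estimated correlation). Immediate early genes (10 up and 2 down of 27, median 0.38, adjusted p = 6.0e-04, or 0.48 with an estimated correlation) and NF-kB genes (4 up and 0 down of 9, median 0.40, adjusted p = 0.0069, or 0.38 with an estimated correlation) were higher with 5-FU, for example FOS (0.93±0.13), NR4A1, a nuclear receptor (1.10±0.12), and SOD2, a mitochondrial superoxide dismutase (0.58±0.08), whereas MYC was lower (-0.78±0.08). Over pairs of libraries the immediate early median ran from 0.04 to 0.63. Ribosomal protein genes (2 up and 1 down of 45, median 0.21, adjusted p = 7.1e-05, or 0.68 with an estimated correlation) and hypoxia and glycolysis genes (4 up and 1 down of 23, median 0.16, adjusted p = 0.045, or 0.38 with an estimated correlation) passed as lists with few single genes. The ribosomal median was 0.386 and 0.289 in library pairs with 5-FU replicate 1, but 0.078 and 0.025 with replicate 2. Quantile normalization ended both list calls, and median scaling ended that of hypoxia and glycolysis. The lists of ribosome biogenesis (3 up and 8 down of 45; median 0.00442, or -0.06 after quantile normalization, mean -0.04, adjusted p = 0.79), histones (0 up and 1 down of 9; median -0.22, adjusted p = 0.55), interferon-stimulated genes (5 up and 2 down of 22; median 0.14, adjusted p = 0.17), cholesterol synthesis (4 up and 5 down of 25; median 0.03, mean -0.01, adjusted p = 0.58), Hedgehog genes (0 up and 2 down of 10; median 0.02, mean -0.12, adjusted p = 0.75), Wnt targets (2 up and 7 down of 16; median -0.39, adjusted p = 0.13) and epithelial and mesenchymal genes (2 up and 4 down of 20; median 0.01, mean -0.06, adjusted p = 0.83) did not pass.

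In total 1383 genes were higher and 2200 lower with 5-FU than with Nutlin3a (limma), 112 and 116 of them at least 2-fold. After median scaling the split was 2020 and 1464, and after quantile normalization 1460 and 1621. Without Nutlin3a replicate 1 or 2 the total of 3583 dropped to 967 or 1555, and without DMSO replicate 1 or 2 to 2388 or 2376. Against DMSO, 409 genes rose with both drugs where independence would give 80.4, and 224 fell with both against 96.4. A further 71 rose with 5-FU and fell with Nutlin3a, and 24 did the opposite. Both comparisons used the same DMSO libraries, which adds to such overlaps: the correlation of both responses over all genes was 0.459, no higher than the 0.496 of simulated data without any drug effect, while the covariance was 0.0676 against 0.0106.

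GLIS2, the zinc finger gene targeted by the siRNAs, was lowered in part. In DMSO it stood at 9.96 FPKM with siCtrl and at 6.53 and 6.66 with siRNA 1 and siRNA 2. In 5-FU it stood at 15.0 with siCtrl and at 9.07 and 6.92. That left 65.6, 66.8, 60.5 and 46.2 percent of the siCtrl value of the same treatment. Untransfected libraries held 5.38 and 4.63 FPKM in DMSO, 5.36 and 6.65 in 5-FU, and 4.86 and 5.36 in Nutlin3a. Both experiments were quantified separately and were not compared by a test. Averaged over both treatments, the knockdown of GLIS2 did not pass with the siRNAs as replicates (-0.68±0.18, adjusted p = 0.74). With each siRNA as its own level, a model chosen after seeing the data, siRNA 2 passed (-0.76±0.15) and siRNA 1 did not (-0.60±0.15, adjusted p = 0.059).

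**Figure D2:**
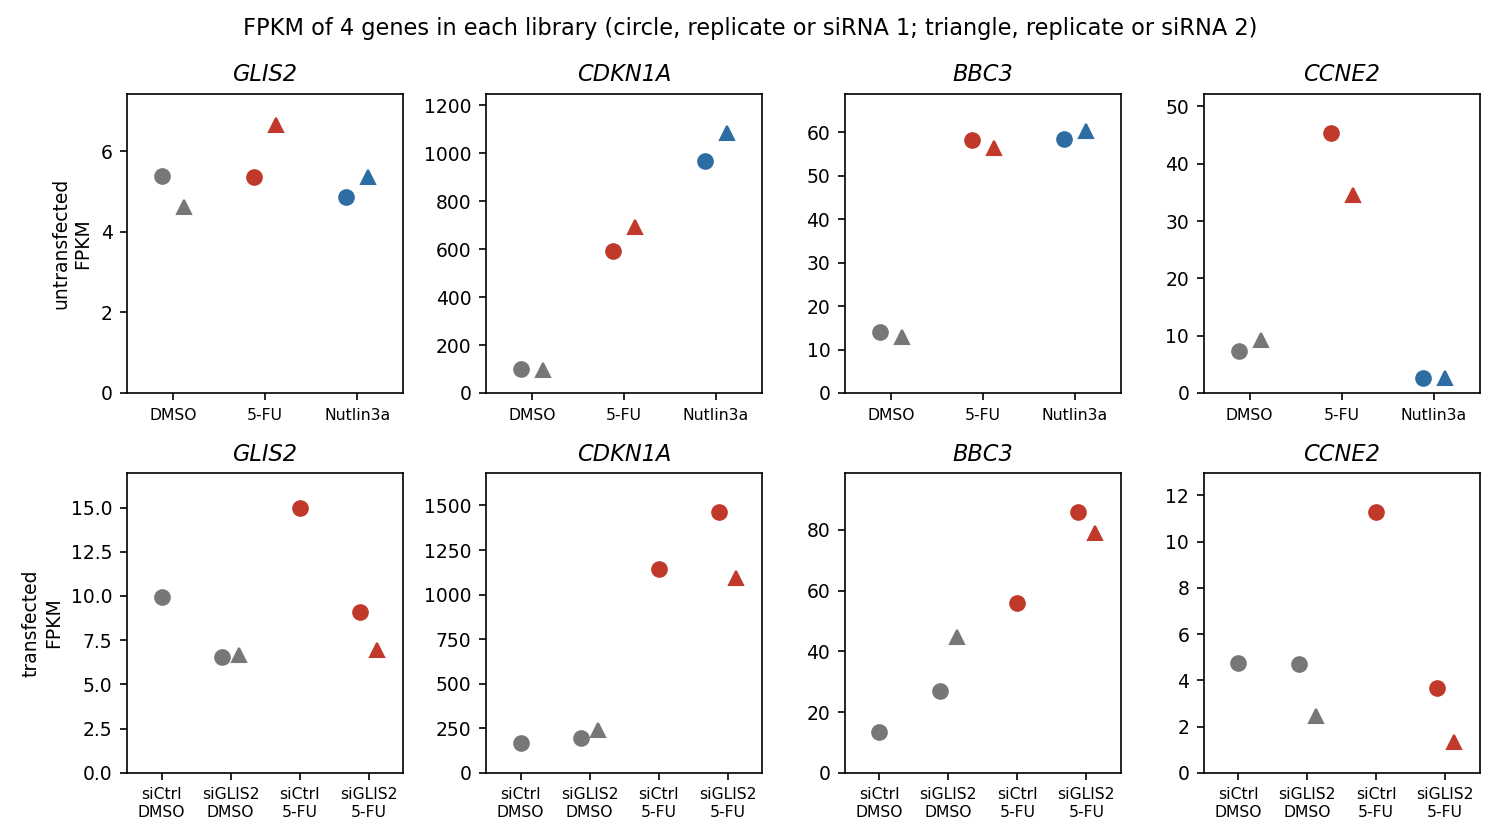
FPKM (vertical axes) of GLIS2, CDKN1A, BBC3 and CCNE2 in each library of the untransfected (upper row) and transfected (lower row) experiments; circles are replicate or siRNA 1, triangles replicate or siRNA 2. CDKN1A went from 98.6 FPKM in DMSO to 643 with 5-FU, and GLIS2 from 15.0 to 9.07 and 6.92 with the siRNAs in 5-FU.

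Some p53 targets had higher values after GLIS2 siRNA, but none passed for the averaged knockdown. In the order siCtrl, siRNA 1, siRNA 2, first in DMSO and then in 5-FU, BBC3 stood at 13.5, 26.8, 44.9 and 56.0, 86.1, 78.9 FPKM (averaged knockdown 0.93±0.26, adjusted p = 0.74) and TP53I3 at 13.8, 31.3, 43.7 and 62.7, 124, 92.9 (1.07±0.23, adjusted p = 0.74). CDKN1A stood at 167, 195, 238 and 1145, 1463, 1093 (0.25±0.22, adjusted p = 0.80), MDM2 at 12.5, 10.5, 13.9 and 55.9, 63.3, 61.5 (0.05±0.19, adjusted p = 0.95), and FAS at 4.65, 5.66, 6.59 and 15.6, 24.4, 18.3 (0.38±0.19, adjusted p = 0.76). As lists, the repair and metabolism targets (24 of 26 with a positive value; median 0.30, adjusted p = 2.9e-06, or 0.59 with an estimated correlation), the cell-death targets (13 of 18; median 0.23, adjusted p = 0.017, or 0.79 with an estimated correlation) and the cell-cycle targets (21 of 29; median 0.19, adjusted p = 0.017, or 0.80 with an estimated correlation) passed with the preset correlation alone. In DMSO their medians were 0.35, 0.23 and 0.28 (adjusted p = 6.3e-05, 0.016 and 0.0085, and 0.59, 0.79 and 0.78 with an estimated correlation), and in 5-FU 0.32, 0.23 and 0.02 (adjusted p = 1.5e-05, 0.059 and 0.10; 0.59, 0.83 and 0.84 with an estimated correlation, and 0.044 for the cell-death list with the siRNA number as a block). The difference of these p53 lists between DMSO and 5-FU did not pass and turned sign for the first 2 of them after quantile normalization, to 0.12 and 0.04 (unscaled interaction medians -0.000298, -0.12 and -0.14, adjusted p = 0.61, 0.50 and 0.39). The siRNAs were unequal: in DMSO the cell-death list had a median of -0.02 for siRNA 1 and 0.48 for siRNA 2, and the cell-cycle list 0.11 and 0.51. In 5-FU the medians were 0.11 and 0.24 for the cell-death list and 0.11 and 0.03 for the cell-cycle list, where the order of the siRNAs was the opposite. The repair and metabolism list had positive medians with both siRNAs, 0.20 and 0.45 in DMSO and 0.34 and 0.30 in 5-FU.

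Cell-cycle genes had lower values with both GLIS2 siRNAs. In the same order, MCM5, of the replicative helicase, stood at 107, 72.5, 80.4 and 129.6, 54.2, 55.7 FPKM (averaged knockdown -0.85±0.16, adjusted p = 0.74), GINS3, of the same helicase complex, at 9.79, 7.02, 6.64 and 11.9, 4.58, 4.19 (-0.86±0.15, adjusted p = 0.71), CDC20 at 209.7, 143, 142 and 111, 64.0, 62.5 (-0.68±0.16, adjusted p = 0.74), and MKI67, a proliferation marker, at 44.5, 27.6, 18.4 and 28.9, 14.5, 16.2 (-0.91±0.22, adjusted p = 0.74). None of the 36 G1/S genes (median -0.76, adjusted p = 1.6e-18, or 0.59 with an estimated correlation) and none of the 35 G2/M genes (median -0.61, adjusted p = 3.8e-18, or 0.59 with an estimated correlation) had a positive averaged value, although none passed singly. The G1/S median was -0.46 in DMSO (adjusted p = 4.8e-09, and 0.73 with an estimated correlation) and -1.07 in 5-FU (adjusted p = 5.0e-24, and 0.59), and the G2/M median -0.64 (adjusted p = 1.1e-19, and 0.59) and -0.57 (adjusted p = 3.8e-13, and 0.59). The larger G1/S deficit in 5-FU passed as an interaction with the preset correlation alone (median -0.59, limma's camera, adjusted p = 3.9e-12, and 0.66 with an estimated correlation). The rotation test fry called 0 lists for the knockdown and for the interaction. In the same order, CCNE2 stood at 4.75, 4.69, 2.44 and 11.3, 3.67, 1.35 FPKM, and its interaction did not pass (-1.51±0.75).

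**Figure D3:**
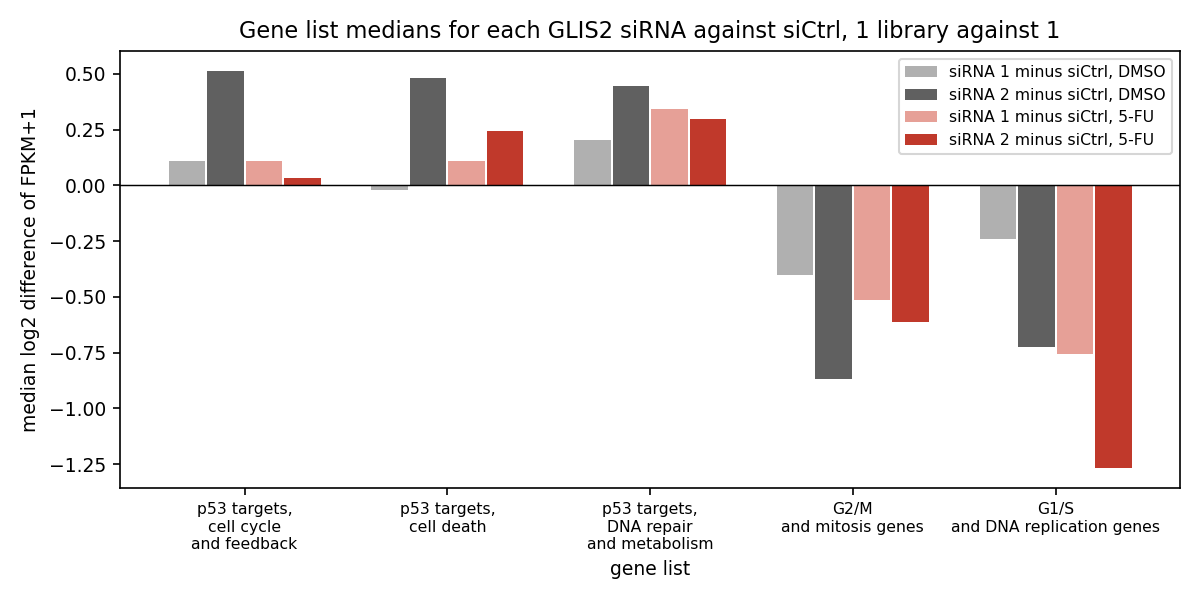
Median log2 difference of FPKM+1 (vertical axis) of 5 gene lists between 1 GLIS2 siRNA library and 1 siCtrl library, for each siRNA in DMSO (gray) and 5-FU (red). G1/S medians were -0.24 and -0.72 in DMSO and -0.75 and -1.27 in 5-FU for siRNA 1 and siRNA 2.

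SLC7A5, SLC29A1 and JUN did not pass for the averaged knockdown. In the same order, SLC7A5, a transporter of large neutral amino acids, stood at 203, 102, 107 and 191, 79.6, 80.8 FPKM (averaged knockdown -1.10±0.16, adjusted p = 0.37), and SLC29A1, a nucleoside transporter, at 55.8, 27.2, 35.5 and 58.2, 24.3, 29.5 (-0.96±0.20, adjusted p = 0.74). JUN, an immediate early transcription factor, stood at 10.7, 26.2, 38.2 and 16.8, 35.1, 47.5 (1.36±0.24, adjusted p = 0.74). Lists that passed with the preset correlation were integrated stress response genes (median -0.34, adjusted p = 5.1e-05, or 0.59 with an estimated correlation), ribosome biogenesis (median -0.19, adjusted p = 3.6e-05, or 0.59 with an estimated correlation), pyrimidine genes (median -0.22, adjusted p = 0.017, or 0.59 with an estimated correlation) and the 3 measured markers of other cell types, CD68, COL1A1 and DES (median 0.45, adjusted p = 0.031, or 0.59 with an estimated correlation, and 0.051 with the siRNA number as a block). The others did not pass: cholesterol synthesis (median -0.23, adjusted p = 0.052), histones (median 0.40, adjusted p = 0.079) and immediate early genes (median 0.19, adjusted p = 0.079), which passed with the siRNA number as a block (adjusted p = 0.038, 0.017 and 0.031), and hypoxia and glycolysis (median -0.17, adjusted p = 0.10), unfolded protein genes (median -0.15, adjusted p = 0.15), Hedgehog genes (median -0.19, adjusted p = 0.19), NF-kB genes (median -0.17, adjusted p = 0.22), interferon-stimulated genes (median 0.03, adjusted p = 0.30), Wnt targets (median -0.09, adjusted p = 0.56), epithelial and mesenchymal genes (median -0.09, adjusted p = 0.72) and ribosomal proteins (median -0.03, adjusted p = 0.81, and a median of 0.00274 after quantile normalization).

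Few features passed for the knockdown in this design, where the spread came from the difference between siRNA 1 and siRNA 2 and the siCtrl groups held 1 library each. Of 11840 features, limma called 25 for the averaged knockdown, all lower and all short RNA features such as SNORD56, a small nucleolar RNA at 67.4 and 68.7 FPKM with siCtrl and listed at 0 with both siRNAs. It called 2 up and 12 down for DMSO, 2 and 22 for 5-FU, and 10 and 19 for the interaction. Without short RNA features, which this library type measures poorly, 0 genes passed in all of these (793, 220, 333 and 11 at an unadjusted p under 0.05). With the siRNA number as a block the counts were 258 (97 up and 161 down), 27, 47 and 49. Leaving out any of the 4 siGLIS2 libraries, siRNA 1 or 2 in DMSO or in 5-FU, gave 0 calls for the averaged knockdown and for the interaction. The count for DMSO was 0 without siRNA 1 in DMSO and 7 and 9 without siRNA 1 and siRNA 2 in 5-FU, and the count for 5-FU was 14 without siRNA 2 in DMSO and 15 without siRNA 2 in 5-FU.

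With each siRNA as its own level over both treatments, chosen after seeing the data, siRNA 1 raised 240 and lowered 215 of 11623 genes, and siRNA 2 raised 1494 and lowered 1576 (limma). The spread in this model was the departure from added siRNA and drug effects, as no library had a replicate. The siRNA 1 count was lower with short RNA features kept and higher after quantile normalization. Genes that passed with both siRNAs included JUN (1.12±0.13 for siRNA 1 and 1.60±0.13 for siRNA 2), TP53I3 (1.05±0.23 and 1.08±0.23), SLC7A5 (-1.12±0.15 and -1.08±0.15), SLC29A1 (-1.12±0.14 and -0.80±0.14), AURKA (-0.88±0.13 and -0.74±0.13), MCM5 (-0.90±0.20 and -0.80±0.20) and STC2, a secreted glycoprotein gene (-0.55±0.12 and -0.54±0.12). BBC3 passed with siRNA 2 (1.08±0.24) and not with siRNA 1 (0.78±0.24, adjusted p = 0.12). CDKN1A (0.29±0.21, adjusted p = 0.48 and 0.22±0.21, adjusted p = 0.47) and MDM2 (-0.03±0.15, adjusted p = 0.92 and 0.14±0.15, adjusted p = 0.53) passed with neither, although CDKN1A passed with siRNA 2 after quantile normalization (0.22) and without siRNA 2 in 5-FU (0.54). In the G1/S list 3 genes fell with siRNA 1, or 16 over the list alone, and 35 of 36 with siRNA 2. In the G2/M list 6 fell with siRNA 1, or 26 over the list alone, and 30 of 35 with siRNA 2. Both siRNAs raised 116 genes where independence would give 30.8 and lowered 80 against 29.2, and 33 genes passed in opposite directions. Both were measured against the same siCtrl libraries, which adds to this overlap. Over all genes the correlation was 0.378, below the 0.501 of simulated data without an effect, and the covariance 0.0481 against 0.0110. The simulation held no departure of siCtrl common to both treatments, which would raise the covariance as well. The count for siRNA 1 moved as single libraries were left out. Without a siRNA 2 library the siRNA 1 fold changes stayed the same, for example MDM2 at -0.03. There the estimate of the spread, not the fold changes, moved the count. For siRNA 2 it was 1902 and 2031 without the siCtrl library in DMSO and in 5-FU, and 4695 and 5473 without the siRNA 2 library in DMSO and in 5-FU. The split turned as well, for siRNA 1 without a siRNA 2 library again through the estimate of the spread. For siRNA 1 it was 227 up and 346 down without siCtrl in DMSO and 276 up and 119 down without siCtrl in 5-FU, 187 up and 95 down without siRNA 1 in DMSO, and 1455 up and 2140 down and 1429 up and 2121 down without siRNA 2 in DMSO and in 5-FU. For siRNA 2 it was 806 up and 1096 down and 1115 up and 916 down without siCtrl in DMSO and in 5-FU, and 1800 up and 2895 down and 3203 up and 2270 down without siRNA 2 in DMSO and in 5-FU.

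5-FU also raised p53 targets and lowered mitotic genes as lists in transfected cells. CDKN1A went from 167 to 1145 FPKM with siCtrl (averaged over siRNAs 2.66±0.22) and MDM2 from 12.5 to 55.9 (2.17±0.19). Both were among the 20 up and 8 down that limma called, most of which were short RNA features. BBC3 (1.60±0.26, adjusted p = 0.31), FAS (1.60±0.19, adjusted p = 0.14) and TP53I3 (1.81±0.23, adjusted p = 0.19) did not pass. As lists, cell-cycle (median 1.20, adjusted p = 3.6e-29, or 0.59 with an estimated correlation), cell-death (median 1.01, adjusted p = 2.5e-22, or 0.59 with an estimated correlation) and repair and metabolism targets of p53 (median 0.56, adjusted p = 5.1e-19, or 0.59 with an estimated correlation) were higher and G2/M genes lower (median -0.85, adjusted p = 8.7e-24, or 0.59 with an estimated correlation). Adjusted over the list alone 21, 15 and 8 members rose and 25 fell. Immediate early genes (median 0.31, adjusted p = 4.8e-09, or 0.59 with an estimated correlation), NF-kB genes (median 0.24, adjusted p = 0.0073, or 0.65 with an estimated correlation), epithelial and mesenchymal genes (median 0.14, adjusted p = 0.017, or 0.59 with an estimated correlation), unfolded protein genes (median -0.33, adjusted p = 8.5e-04, or 0.59 with an estimated correlation), G1/S genes (median -0.27, adjusted p = 0.024, or 0.86 with an estimated correlation) and ribosomal proteins (median 0.06, adjusted p = 0.027, or 0.86 with an estimated correlation) passed with the preset correlation, the last with a median that turned to -0.04 after quantile normalization and an adjusted p of 0.078 with the siRNA number as a block. G1/S genes did not move together with siCtrl (median 0.04) but were lower in 5-FU with siRNA 1 (-0.51) and siRNA 2 (-0.56).

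With the siRNA number as a block, 374 features passed for 5-FU in transfected cells (179 up and 195 down), and without short RNA features in the 4 group means 0 did (936 at an unadjusted p under 0.05, limma). The count with 4 group means was 28, and leaving out siRNA 1 or siRNA 2 in DMSO left 0 or 0 calls, and leaving out either in 5-FU left 3 or 5. In the additive model of siRNA and drug, chosen after seeing the data and without replicate libraries, 486 of 11623 genes rose and 1219 fell. After median scaling the split was 836 and 679, and after quantile normalization 1097 and 1056. There BBC3 (1.47±0.20), FAS (1.61±0.13), ATF3 (1.62±0.10), BTG2 (1.81±0.17), GDF15 (1.48±0.25) and BAX (0.76±0.17) rose and AURKA (-1.28±0.10) fell, and 34 of 35 G2/M genes fell. Its total of 1705 was 802 and 792 without the siRNA 1 library in DMSO and in 5-FU, and 4175 and 4142 without the siRNA 2 library in DMSO and in 5-FU. Across 10917 genes tested in both experiments, 281 rose with 5-FU in both (independence 44.6), 617 fell in both (162) and 5 passed in opposite directions, with a correlation of all fold changes of 0.646. These experiments share no library, and the correlation was 0.585 with 4 group means, over 11031 genes with short RNA features kept. The Spearman correlations were 0.547 in the additive model and 0.585 with 4 group means. Nutlin3a in untransfected cells and 5-FU in transfected cells correlated at 0.555. In all, 5 pairs of responses were compared this way.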

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

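The tests of each siRNA taken singly and of the siCtrl libraries were chosen after the result was seen. Several differences between knockdown and control in their response to 5-FU passed limma's test of the interaction itself: 29 single features, all of them short RNA features that poly(A) libraries measure poorly, and 3 gene lists. Of these lists, G1/S and DNA replication genes had a median interaction of -0.59, pyrimidine genes of -0.21 and cytosolic ribosomal proteins of -0.19 (adjusted p = 3.9e-12, 0.031 and 0.013 with the preset correlation, and 0.66, 0.59 and 0.86 with an estimated correlation). The rotation test fry called 0 lists for the interaction. Across genes the interaction rose with gene length (Spearman correlation 0.371). All 2158 genes under 10 kb had a median of -0.209, near the pyrimidine and ribosomal medians, which are given without subtracting that trend. The ribosomal list turned to 0.02 after quantile normalization and did not pass with the siRNA number as a block (adjusted p = 0.48), and its median was 0.05 for siRNA 1 and -0.42 for siRNA 2. The pyrimidine list did not pass after quantile normalization (adjusted p = 0.066) and had -0.10 and -0.34, and interaction calls of histones (adjusted p = 0.048) and interferon-stimulated genes (0.050) appeared with the block.

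The deficit of G1/S genes after GLIS2 siRNA was larger in 5-FU than in DMSO as a list, led in size by CCNE2, E2F2, MCM5 and GINS3. None of these genes passed the interaction singly. Different scaling of the libraries is argued against as the whole cause by the median of -0.51 after quantile normalization, and a gene length trend by -0.53 after subtracting it. For an off-target effect of a single siRNA, 5-FU was compared with DMSO within each siRNA, values that share no library. The median was -0.51 for siRNA 1 (35 of 36 genes lower) and -0.56 for siRNA 2 (35 of 36). Ribosomal protein genes were lower in the siRNA 2 pair too (-0.26, 44 of 44). None of 10000 random lists of similar expression had a lower median than G1/S genes in either pair. The fall was thus not confined to a single siRNA. The check was set after its values were seen, so it cannot exclude such an effect. An atypical siCtrl library cannot be told apart from a GLIS2 effect with 1 siCtrl library per treatment: the siCtrl difference between 5-FU and DMSO was 0.0397, and those of untransfected pairs were 0.17 to 0.31. An effect of GLIS2 stays open as well, and no mechanism was tested.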

How the results depend on the processing

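Leaving out short RNA features, the additive model of siRNA and drug with its alternatives, the fits with siCtrl and a single siRNA, and the siRNA block and quantile normalization for gene lists were chosen after seeing the data. Unless a reason is given, the cause was not tested. Values of named genes had the same direction and side of the threshold in 2661 cases, lost the call in 112, gained it in 63 and reversed in 18. Several settings, such as no trend or another filter, cannot change a fold change. The tally therefore overstates how far directions were tested. Without a filter the calls were 1816 for 5-FU, 975 for Nutlin3a, 52 for the averaged knockdown, 51 for the interaction and 50 for 5-FU in transfected cells. With a filter at 5 FPKM, which tests fewer genes, they were 9 for the averaged knockdown, 8 for DMSO, 7 for 5-FU, 12 for the interaction, 12 for 5-FU in transfected cells, 231 for siRNA 1 and 1061 for 5-FU in the additive model. The averaged knockdown gave 14 with a pseudocount of 0.1, 15 after median scaling and 1 in the additive model of drug and knockdown, where 5-FU gave 14. siRNA 1 gave 1225 after quantile normalization, and Nutlin3a 2400 without the 5-FU libraries in the fit. With siCtrl and siRNA 1 alone, in the additive model of drug and knockdown, so that libraries and model changed together, the knockdown gave 2251 and 5-FU 2777 calls, and with siRNA 2 alone 2453 and 817. Short RNA features left out gave 0 calls in all 5 contrasts of transfected cells, by limma (793, 220, 333, 11 and 936 at an unadjusted p under 0.05), and kept in the additive model 45 for siRNA 1 and 985 for 5-FU. With the siRNA number as a block, calls were 258 for the averaged knockdown, 27 in DMSO, 47 in 5-FU, 49 for the interaction and 374 for 5-FU. Replicate numbers of untransfected cells did not pair the samples (correlations -0.03, -0.04 and 0.20), and a replicate block gave 3091, 1608 and 3676 calls. In gene lists of transfected cells the block also ended the call of markers of other cell types in DMSO (adjusted p = 0.031, and 0.051 with the block), and changed no other call beyond those given. It was not run for gene lists of untransfected cells. With an estimated correlation the called gene lists went from 14 to 2 for 5-FU, from 9 to 2 for Nutlin3a, from 9 to 0 between drugs, and in transfected cells from 9, 10, 7, 3 and 10 to 0. Median scaling ended the list calls of ribosome biogenesis for 5-FU (adjusted p = 0.080) and of hypoxia and glycolysis between drugs (0.060), and added cholesterol synthesis for the averaged knockdown (0.034) and cell-death targets and hypoxia and glycolysis for the knockdown in 5-FU (0.048 and 0.035). Quantile normalization ended those of ribosomal proteins for 5-FU (0.051), between drugs (0.73), for the interaction (0.82) and for 5-FU in transfected cells (0.30), of hypoxia and glycolysis for 5-FU (0.31) and between drugs (0.21), of pyrimidine genes for Nutlin3a (0.052) and the interaction (0.066), of ribosome biogenesis for Nutlin3a (0.073), of epithelial and mesenchymal genes for 5-FU in transfected cells (0.072) and of markers of other cell types for the averaged knockdown (0.052). It added ribosomal proteins for Nutlin3a (0.047), cell-cycle targets of p53 between drugs (0.049), NF-kB and interferon-stimulated genes for the interaction (0.046 and 0.030), and cell-cycle targets, cell-death targets and NF-kB genes for the knockdown in 5-FU (0.033, 0.021 and 0.035). Without short RNA features, lists added were NF-kB genes for the interaction (adjusted p = 0.042), cholesterol synthesis and histones for the averaged knockdown (0.034 and 0.049), and cell-death targets, NF-kB genes and hypoxia and glycolysis for the knockdown in 5-FU (0.043, 0.043 and 0.049), and none was lost. The correlation of 5-FU responses across experiments was 0.527 with a pseudocount of 0.1. Leaving out each library in turn, but in the 4 group means only the siGLIS2 libraries, gave 628 to 4152 calls for 5-FU, 446 to 2403 for Nutlin3a, 967 to 4721 between drugs, 0 each time for the averaged knockdown, 0 to 16 in DMSO, 14 to 25 in 5-FU, 0 each time for the interaction, 0 to 5 for 5-FU in transfected cells, 124 to 3595 for siRNA 1, 1902 to 5473 for siRNA 2 and 792 to 4175 for 5-FU in the additive model. A group left with 1 library was assumed to vary like the others. Leaving out a siRNA 2 library changed the estimate of the spread and not the siRNA 1 fold changes. GLIS2 for Nutlin3a was -0.00301 after median scaling and -0.0412 after quantile normalization and -0.0633 to 0.12 with each library left out, the sign turning without DMSO replicate 2 or without Nutlin3a replicate 2. BBC3 for 5-FU against Nutlin3a was 0.0549 after median scaling. BAX for 5-FU against Nutlin3a was -0.0600 after quantile normalization. MDM2 for the averaged knockdown was -0.0312 with siCtrl and siRNA 1 alone and -0.0418 to 0.15 with each library left out, the sign turning without siRNA 2 in DMSO. CDKN1A for siRNA 2 was -0.10 to 0.54 with each library left out, the sign turning without siRNA 2 in DMSO. MDM2 for siRNA 1 was 0.0439 after quantile normalization and -0.24 to 0.18 with each library left out, the sign turning without siCtrl in DMSO or without siRNA 1 in DMSO. KLK6 for siRNA 2 was -0.0586 to 0.31 with each library left out, the sign turning without siRNA 2 in DMSO. KRT23 for siRNA 2 was -0.10 to 0.0265 with each library left out, the sign turning without siCtrl in 5-FU or without siRNA 2 in 5-FU. ANXA2 for siRNA 2 was -0.0384 to 0.13 with each library left out, the sign turning without siRNA 2 in DMSO. CYR61 for siRNA 1 was -0.21 to 0.33 with each library left out, the sign turning without siCtrl in 5-FU or without siRNA 1 in 5-FU. None of these genes was called in that contrast in the fit reported. CDKN1A for siRNA 2 gained the call after quantile normalization (0.22) and without siRNA 2 in 5-FU (0.54), and KLK6 for siRNA 2 without siRNA 2 in 5-FU (0.31). Repeated names as separate features were not run for untransfected cells, which have no repeated names. Without counts, the depth behind a value near 0 FPKM is unknown, and small changes of such genes were not detectable.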

Other observations

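The model with each siRNA as its own level was chosen after the data were seen, and whether the siRNAs differed in a gene was not tested. Many genes passed with a single siRNA. With siRNA 1, KLK6, a serine protease gene, rose (1.87±0.15; siRNA 2 0.13±0.15), as did KRT23, a keratin (1.56±0.12; -0.04±0.12), whereas VCL, which encodes the adhesion protein vinculin, stood at 43.6, 14.1, 32.6 and 39.8, 14.7, 38.6 FPKM in the order siCtrl, siRNA 1, siRNA 2 in DMSO and then in 5-FU (-1.47±0.14 for siRNA 1 and -0.23±0.14 for siRNA 2). ANXA2, annexin A2, fell with siRNA 1 (-1.44±0.18; siRNA 2 0.05±0.18), and so did SREBF2, the transcription factor of cholesterol synthesis (-1.37±0.12; 0.30±0.12), in a list of cholesterol genes with 0 up and 5 down of 25 for siRNA 1 and 5 up and 3 down of 25 for siRNA 2. With siRNA 2, ANKRD1, a target of mechanical signaling, rose (2.11±0.15; siRNA 1 0.17±0.15), together with CYR61 (1.90±0.16; 0.06±0.16), CPA4, a carboxypeptidase (2.42±0.17; 0.39±0.17), and FOLR1, a folate receptor (1.80±0.15; 0.40±0.15). ELK3, an ETS factor (-1.90±0.12; siRNA 1 -0.49±0.12), and PTGES3, a cochaperone (-1.67±0.14; -0.33±0.14), fell with siRNA 2. Histone genes had 7 up and 0 down of 11 with siRNA 2, for example HIST1H2BD at 6.42, 6.98, 31.6 and 7.02, 9.84, 32.7 FPKM in the same order, and 0 up and 0 down of 11 with siRNA 1. With both treatments pooled, siRNA and siCtrl libraries overlapped for TP53I3 and AURKA, which passed with both siRNAs, and for BBC3, which passed with siRNA 2. Pooling leaves the difference between DMSO and 5-FU in these ranges. Within each treatment, between single libraries, TP53I3 was higher with either siRNA than with siCtrl, and BBC3 was higher with siRNA 2.

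G1/S and DNA replication genes, among them CCNE2, CCNE1, E2F2 and UHRF1, were higher with 5-FU than with Nutlin3a. Different scaling of the libraries is argued against as the whole cause by a list median of 0.85 after quantile normalization, a single divergent library by the lowest median among the 4 pairs of libraries (0.83), and a gene length trend by 0.95 after subtracting it. A different effect of both drugs on the cell cycle stays open and was not tested, since no cell-cycle profile was analysed here.

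Longer genes tended to be lower with 5-FU. Of genes shorter than 10 kb 361 rose and 208 fell (median 0.09), and of those longer than 100 kb 67 rose and 425 fell (median -0.21). The Spearman correlation across genes was -0.281 for 5-FU and 0.0682 for Nutlin3a. Low expression is argued against by -0.293 in the third of genes with the highest mean FPKM. The length of the spliced transcript cannot be told apart (partial correlation -0.152, between the bounds set for either answer), and neither can a divergent library (highest pair -0.151): the same trend was 0.282 between both 5-FU libraries and 0.188 between both DMSO libraries, about as large. In transfected cells it was -0.321 with siCtrl, -0.220 with siRNA 1 and 0.169 with siRNA 2, so an effect of 5-FU on long genes was not separated from differences between libraries.

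The 3 DMSO and 3 5-FU libraries of transfected cells can be split in 10 ways, too few for a share under 0.05: the real split gave 20 called features in limma with these groups alone, the highest other split 5.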
